A study of Drosophila melanogaster with 8 samples.

How the data were processed

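Heads of unmated male Drosophila melanogaster of the wild-type strain Oregon-R were compared on 8 two-colour cDNA arrays. Per the labels' protocols, flies ate pentylenetetrazole at 8 mg/ml for 7 days and then vigabatrin at 24 mg/ml for 3 days, and heads were taken on day 10. In a second arm the flies were kept for 4 more days on normal food and heads were taken on day 14. Control flies stayed on normal food and were harvested on the same day. Each array paired 1 pool of treated heads with 1 parallel pool of control heads, so no control was shared between arrays or days. The labels name 4 biological replicates per day. Treated RNA carried Cy5 and control RNA Cy3 in replicates 1 and 2 of each day, and the dyes were swapped in replicates 3 and 4.

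The deposited table held 1 log2 ratio per spot and array. Per the labels' protocols, the authors scanned the slides with a GenePix 4000A scanner, quantified the images with GenePix Pro 6.0 and applied a ratio-based normalization in Acuity 4.0. Per the submitters' design text, the authors kept spots with an intensity of at least 100, a signal of at least 2 times the background, under 3% saturated pixels, a regression R2 of at least 0.6 and a signal-to-noise ratio of at least 3, measured in at least 3 replicates. Some clones have deposited values on fewer than 3 arrays of a day, so that replicate filter does not hold within each day. The design text ends before a statistical test is named, so the tests were chosen here. The log2 scale was read from the values deposited by the authors, which were centred near 0 on both sides and capped at 16.61 on 3 spots. Scanner intensities were not used here, so the strength of the signal over background behind a ratio is not known beyond those filters.

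Neighbouring spots carried the same annotation in all 7609 annotated pairs and were treated as 2 spots of 1 clone. The 27648 spots thus made 13824 clones, of which 7558 had 1 gene in the platform annotation, 51 had several and 6215 had none. Of the 7558, 7447 matched the RefSeq gene table of the Release 6 assembly by gene ID and took their current symbol from it, and 111 kept the symbol of the annotation. That table served for names only. The labels name no genome build, and no coordinates are given. Clones with several genes or none entered the tests and the counts but are not named. The number of spots with a value ranged from 8419 to 20241 per array, and 4540 spots had no value on any array.

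The direction of the deposited ratio is not stated. It was taken as channel 1 over channel 2 of the labels, that is Cy5 over Cy3, and the sign was turned on the 4 arrays with treated RNA in Cy3, so that values below 0 mean lower in treated heads. This direction is called likely from the dyes and channel order in the labels alone, and the values do not settle it. Compared before turning, the ratios of all clones correlated above 0 in 8 of 8 pairs of arrays across days and 4 of 4 within a day when the dye orientation was the same, and in 2 of 8 and 2 of 8 when it was opposite. A treatment effect in Cy5 over Cy3 ratios gives that pattern, but so does a dye bias in ratios that had been turned already. Print-block medians, which follow the slide and would keep their sign in Cy5 over Cy3 ratios, correlated above 0 in 11 of 16 pairs of opposite orientation, namely in 9 of 9 pairs among 6 of the arrays, in 1 of the 6 that set day-10 replicate 4 or day-14 replicate 1 against one of these, and in the pair of those 2. This grouping was made after the values were seen. In pairs of the same orientation those 2 arrays also lay above 0 in 1 of 6, so they stand apart in either orientation. Every direction given below rests on this choice.

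The main model was fitted with limma 3.58.1 in R 4.3.3 on the turned values as deposited, with a coefficient for each day and a gene-specific dye term common to both days. Clones measured on at least 3 of the 4 arrays of each day and in both dye orientations were tested, which left 4563. Tested were day 10 and day 14 against 0, their difference and their mean. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Where values are called centred, the median of each array was subtracted first. This setting is given beside the main one for most results because the medians of the turned arrays ran from -0.48 to 0.24. A further setting, local centring, was chosen after seeing the data. It subtracted from each clone the median of its neighbours within 2 rows and 3 clones in the same print block, with at least 5 neighbours, and left 4255 clones. The 48 print blocks of 576 spots were inferred from the number and order of spots. Neighbouring clones of a row had correlated ratios, with a Spearman coefficient between 0.26 and 0.48 per array, which fell to between 0.06 and 0.28 after local centring. Each array's clones are not independent of their neighbours for that reason.

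Gene lists were tested with cameraPR of limma on moderated t values, with 1 clone per gene, a preset correlation of 0.01 and at least 5 measured genes. An estimated correlation was the alternative, which could be smaller than the preset one. This test sets the genes of a list against the other genes, so its p-values do not measure how a list varied between arrays. Of 28 lists, 25 could be tested. The lists on GABA, acetylcholine and UDP-glycosyltransferases had too few measured members. In 3 cases a symbol written in a list belongs to another gene in the RefSeq table and was left out (don, bl and qm). Named genes followed a fixed rule. For each day they were the 12 highest and 12 lowest log2 ratios among genes past the threshold with the same sign on every measured array, or else the 6 highest and 6 lowest among the 100 lowest p-values, as values. For each list they were up to 4 members past the threshold, or else the 2 with the lowest p-values. The target genes of both drugs and Gad1 were always included. The model, the tests, the lists, this rule and the first set of alternatives were fixed before the data were examined.

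The procedure was tested on simulated data with the missing values of the 4563 clones and their spread after array-median centring. At a true log2 ratio of 0.5 it recovered 54% of changed clones at day 10, 52% at day 14, 9% for the difference between days and 86% for the mean of both. At a true log2 ratio of 1 the shares were 99%, 100%, 81% and 100%. False calls numbered 21, 5, 7 and 17. Each true ratio had 100 changed clones. At day 10 the 21 stood beside 54 and 99 recovered clones, and for the mean of both days the 17 beside 86 and 100. Except at day 14, false calls thus made up more than the nominal share of 0.05 of the calls in this simulation. The simulation had no local slide pattern, so these shares do not cover that source of error. The number of arrays, 4 per day, limits the precision. Alternatives were the dye term, the samples in the fit, the direction of the ratio, centring, scaling, array weights, robust variance estimation, the filter on missing values, single spots, a threshold of 0.1, a replicate block, and each array left out in turn. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.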

Results

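Transcript levels were compared between heads of drug-fed and control male flies at the end of a drug sequence (day 10) and after a further 4 days on normal food (day 14). Pentylenetetrazole is a convulsant that blocks GABA-gated chloride channels, and vigabatrin is an antiepileptic drug that inactivates GABA transaminase. The design asks which transcripts differ when vigabatrin follows pentylenetetrazole, and whether they still differ once both drugs are withdrawn. Each day had 4 arrays, and each array set a treated pool against a control pool of the same day. Values are log2 ratios of treated over control, with the direction taken as likely from the dye labels. At day 10 the arrays held 19731, 20241, 14592 and 8419 spots with a value (replicates 1 to 4), and at day 14 they held 9266, 15595, 15866 and 13282. Both spots of a clone were related with a Spearman coefficient of 0.61 to 0.84 per array.

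At day 10, lists of fat body, immune and glial genes were lower in treated heads, although with an estimated correlation the immune list did not pass as deposited (adjusted p = 0.12). After array-median centring 3 of 12, 1 of 5 and 1 of 5 of their genes passed as lower over all genes tested. The named gene with the largest decrease, CG2233, has no function assigned here and fell by 1.59 ± 0.22 on the log2 scale relative to the median of each array (SE, n = 4 arrays, limma adjusted p = 0.0105). The storage protein gene Lsp2 fell by 0.90 ± 0.17 (n = 3, adjusted p = 0.0283), and sxe2, a lipase-family gene of male heads, fell by 1.12 ± 0.16 (n = 3, adjusted p = 0.0105). Drsl5, a member of the drosomycin family of antifungal peptides, fell by 0.84 ± 0.11 (n = 4, adjusted p = 0.0105). Tret1-1, a trehalose transporter of the glia that form the blood-brain barrier, fell by 0.71 ± 0.10 (n = 4, adjusted p = 0.0105).

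Other single genes were lower as well. Miox, which encodes the inositol-degrading enzyme myo-inositol oxygenase, had a centred log2 ratio of -1.04 ± 0.18 (adjusted p = 0.0172), and Galk, the galactokinase gene, had -1.08 ± 0.22 (adjusted p = 0.0432). One clone of apolpp, the gene of the main haemolymph lipoprotein, had -1.07 ± 0.16 (adjusted p = 0.0116), and Cyt-b5-r, a cytochrome b5-related gene, had -1.06 ± 0.18 (adjusted p = 0.017). The cytochrome P450 gene Cyp313a1 had -1.32 ± 0.18 (adjusted p = 0.0105). Alg7, which acts in the first step of N-glycan assembly, had -1.02 ± 0.15 (adjusted p = 0.011). The uncharacterised genes CG16926, CG11400 and CG17108 had -1.29, -0.98 and -0.95 (adjusted p = 0.0245, 0.017 and 0.0394). The mitochondrial ribosomal protein gene mRpS34 passed the threshold as deposited (adjusted p = 0.0137) but not after centring, where it had -1.20 ± 0.28 (adjusted p = 0.0563).

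Of these genes and the named list members below, 9 passed the threshold as deposited, after array-median centring and after local centring, namely CG2233, CG16926, sxe2, Cyt-b5-r, Miox, Tret1-1, Obp99b, Drsl5 and Lsp2. Their locally centred values ran from -1.35 for CG2233 (adjusted p = 0.018) to -0.71 for Tret1-1 (adjusted p = 0.0309). Galk, Alg7, CG11400 and CG17108 did not pass after local centring, with -1.07, -0.99, -0.64 and -0.65 (adjusted p = 0.0989, 0.0712, 0.0768 and 0.152). Cyp313a1 and that clone of apolpp had too few measured neighbours for a local value. With day-10 replicates 1 to 4 left out in turn, 0, 6, 8 and 3 of the 9 genes passed after array-median centring, 3, 4, 1 and 4 after local centring, and 9, 8, 9 and 9 as deposited. With day-14 replicates 1 to 4 left out these counts were 9, 9, 8 and 7 after array-median centring, 8, 8, 6 and 4 after local centring, and 9 each as deposited.

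**Figure D1:**
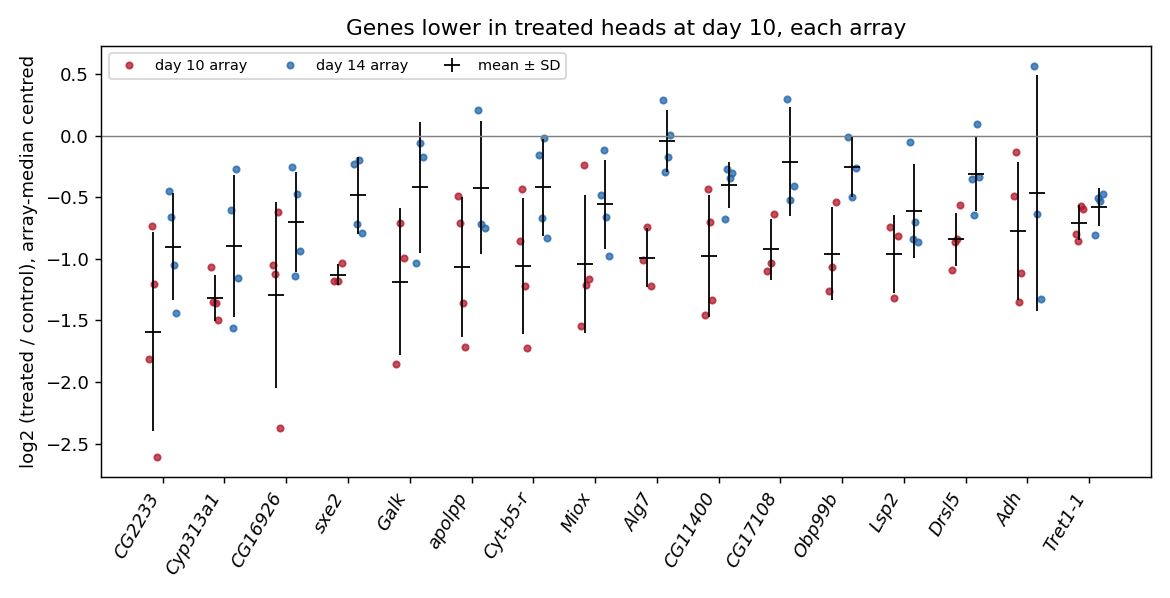
Log2 ratios of treated over control heads (vertical axis), relative to the median of each array, for 16 genes along the horizontal axis, with 1 point per array (day 10 red, day 14 blue) and bars for the mean ± SD. At day 10 CG2233 had the lowest fitted ratio, -1.59, and the day-14 ratios were nearer to 0 for most genes, which a selection at day 10 alone can bring about.

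The list of fat body and lipid storage genes was lower as a group, with a median of -0.55 as deposited and -0.34 after centring over 12 measured genes (cameraPR adjusted p = 0.00237 and 0.000434). Of the 12, 4 fell when adjusted over all genes tested (Obp99b, Lsp2, Adh and a second clone of apolpp), and 11 fell when adjusted over the list alone. After centring these counts were 3 and 4, and apolpp at -0.68 did not pass over all genes tested (adjusted p = 0.0563). Obp99b, an odorant-binding protein gene also expressed in fat body, fell by 0.91 ± 0.16 and Adh, the alcohol dehydrogenase gene, fell by 0.77 ± 0.15 relative to the array median (adjusted p = 0.0276 and 0.0294). After local centring Adh had -0.79 (adjusted p = 0.0714), while this clone of apolpp fell by 1.18 ± 0.12 (adjusted p = 0.00802). The fatty acid desaturase gene Desat1 and the fatty acid synthase gene FASN1 had -0.29 each after centring in the clones that stand for them in the list, and neither clone passed as deposited (adjusted p = 0.0527 and 0.057), while this clone of Desat1 had -0.68 and passed after local centring (adjusted p = 0.016). A second clone of Desat1 had -0.885 and passed as deposited (adjusted p = 0.0115), and had -0.669 after array-median centring and -0.596 after local centring, where it did not pass (adjusted p = 0.0546 and 0.0528). The yolk protein gene Yp2 lay the other way at 0.69 after centring and did not pass over all genes tested (adjusted p = 0.15), but was the 1 gene that passed as higher when adjusted over the list alone. The median of this list lay below the array median on 4 of 4 day-10 arrays, and also on the day-14 arrays (-0.03, -0.34, -0.31 and -0.35). With the ratios read as already turned, a list setting added after the results were seen, the list lay the other way, at 0.14 as deposited, 0.29 after array-median and 0.24 after local centring, and did not pass (adjusted p = 0.115, 0.174 and 0.332).

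Of 5 measured antimicrobial and immune genes, 3 fell as deposited when adjusted over all genes tested and 4 when adjusted over the list alone, with a list median of -0.81 (adjusted p = 0.00237; adjusted p = 0.12 with an estimated correlation). After centring the median was -0.55 (adjusted p = 0.000798; adjusted p = 0.0175 with an estimated correlation), and Drsl5 alone passed over all genes tested, while 3 were lower when adjusted over the list alone. Read as already turned, neither this list nor the glial one passed (adjusted p = 0.607 and 0.784 as deposited). Drs, the gene of the antifungal peptide drosomycin, had -0.55 ± 0.16, and nec, a serpin gene that restrains Toll signalling, had -0.62 ± 0.15 (adjusted p = 0.0871 and 0.0596). Of 5 measured genes of glia and the blood-brain barrier, 4 fell as deposited by both adjustments, with a median of -0.59 (adjusted p = 0.00489; adjusted p = 0.0469 with an estimated correlation). These were Tret1-1, the astrocyte gene alrm, the glutamine synthetase gene Gs2 and the septate junction gene Gli. After centring the median was -0.37 (adjusted p = 0.00862), and alrm, Gs2 and Gli had -0.58, -0.37 and -0.32 without passing over all genes tested (adjusted p = 0.0574, 0.0742 and 0.168). The engulfment receptor gene drpr had 0.43 (adjusted p = 0.0563). Adjusted over the list alone, 4 of the 5 were lower after centring and 1, drpr, was higher.

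Cytoplasmic ribosomal protein genes had a median of -0.48 over 16 genes (adjusted p = 0.0121; adjusted p = 0.252 with an estimated correlation), and as deposited 9 fell when adjusted over all genes tested and 11 when adjusted over the list alone, among them RpL23, RpL15, RpL39 and RpS7. After centring the median was -0.27 (adjusted p = 0.00862; adjusted p = 0.0113 with an estimated correlation), with 0 lower over all genes tested and 3 when adjusted over the list alone. Cytochrome P450 genes had a median of -0.35 over 23 genes (adjusted p = 0.0364; adjusted p = 0.452 with an estimated correlation), with 7 lower over all genes tested and 9 when adjusted over the list alone. Cyp4d21, Cyp28d1 and Cyp4e2 were among them, at -0.67, -0.63 and -0.49 after centring, where none of these 3 passed (adjusted p = 0.14, 0.107 and 0.0733). In that setting the list had -0.12 (adjusted p = 0.0206), which did not pass with an estimated correlation (adjusted p = 0.2), with 1 gene lower by either adjustment. Odorant-binding and chemosensory genes had a median of -0.53 over 9 genes (adjusted p = 0.0364; adjusted p = 0.249 with an estimated correlation), with 4 and 6 lower by the same adjustments, including Obp19d, Obp57c and Obp56d. After centring the median was -0.34 (adjusted p = 0.0206; adjusted p = 0.0175 with an estimated correlation), with 1 lower over all genes tested, and 5 lower and 1 higher when adjusted over the list alone. After local centring these 3 lists had adjusted p = 0.121, 0.274 and 0.449, whereas the fat body, immune and glial lists had adjusted p = 1.04e-09, 0.00533 and 0.0122. Among other tested clones of genes named here, Obp56d had -0.444 and 0.096, Obp19d had -0.392 and RpL39 had -0.446 as deposited. None passed (limma adjusted p = 0.0817, 0.564, 0.064 and 0.0895). After array-median centring those Obp56d clones had -0.192 and 0.313. Antioxidant genes, which did not pass as deposited, passed after local centring with a median of -0.23 (adjusted p = 0.0251; adjusted p = 0.0644 with an estimated correlation). Without day-10 replicate 3, 3 lists passed as deposited instead of 6. Without day-10 replicate 4, 3 passed after centring, and of the 4 lists that passed after local centring, 1 did without day-10 replicate 2 and 2 did without day-10 replicate 3.

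Energy metabolism genes did not pass as lists at day 10 by cameraPR. Oxidative phosphorylation genes had a median of -0.34 over 24 genes (adjusted p = 0.0879), with 9 lower over all genes tested and 13 when adjusted over the list alone, including ATPsynbeta, ATPsynG, SdhD and levy. Another tested clone of ATPsynG had -0.45 and did not pass (limma adjusted p = 0.0958). Glycolysis and trehalose genes had -0.38 over 15 genes (adjusted p = 0.0636), with Gpdh1, UGP, Eno and Pgi past the threshold as deposited. Tricarboxylic acid cycle genes had -0.39 over 9 genes (adjusted p = 0.0651), with ScsbetaA, Ogdh and Scsalpha1 past it. These are log2 ratios as deposited, where the median of all clones was -0.21, and 0 of the 11 genes named passed after centring. In that setting these 3 lists had adjusted p = 0.154, 0.0891 and 0.0891, and Gpdh1 had -0.57 ± 0.14 (adjusted p = 0.0582). An alternative test, fry of limma, sets a list against 0 over clones with complete values. By fry, oxidative phosphorylation and glycolysis genes passed as deposited (adjusted p = 0.000414 and 0.00617) but not after centring (adjusted p = 0.227 and 0.267). Ribosomal and P450 genes passed by fry as deposited (adjusted p = 0.00476 and 0.00523) and after centring (adjusted p = 0.0253 each). The fat body, immune and glial lists had fewer than 5 genes with complete values, so fry could not test them.

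Neuronal lists did not pass at day 10 by cameraPR. By fry, glutamate signalling passed as deposited (adjusted p = 0.00917) but not after centring (adjusted p = 0.804). Adjusted p-values of cameraPR as deposited were 0.956 for synaptic vesicle genes, 0.791 for ion channels, 0.791 for glutamate signalling, 0.956 for monoamine genes, 0.956 for neuropeptides, 0.791 for phototransduction, 0.702 for learning and memory, and 0.956 for clock genes, and after centring the smallest was 0.475. One clock gene, cry, encoding the circadian photoreceptor, passed as deposited (adjusted p = 0.0174) and had -0.53 ± 0.15 after centring (adjusted p = 0.0846). Gad1, which makes GABA and is not itself the target of either drug, had 0.08 ± 0.14 after centring (adjusted p = 0.798). Of the drug target genes, the GABA-gated channel gene Lcch3 was tested and had 0.25 ± 0.20 after centring (adjusted p = 0.527). Gabat, the gene of GABA transaminase, was measured on 3 day-10 and 2 day-14 arrays and was not tested, and the other 2 channel genes, Rdl and Grd, are not named in the array's annotation. Lists marking other tissues did not pass either, with adjusted p = 0.791 for muscle, 0.319 for midgut enzymes, 0.762 for testis and accessory gland, and 0.956 for cuticle. Glutathione S-transferases (adjusted p = 0.791), heat shock genes (adjusted p = 0.906), the proteasome (adjusted p = 0.791) and antioxidant genes (adjusted p = 0.791) did not pass as deposited. After centring the smallest adjusted p among these lists of other tissues and of stress was 0.432.

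**Figure D2:**
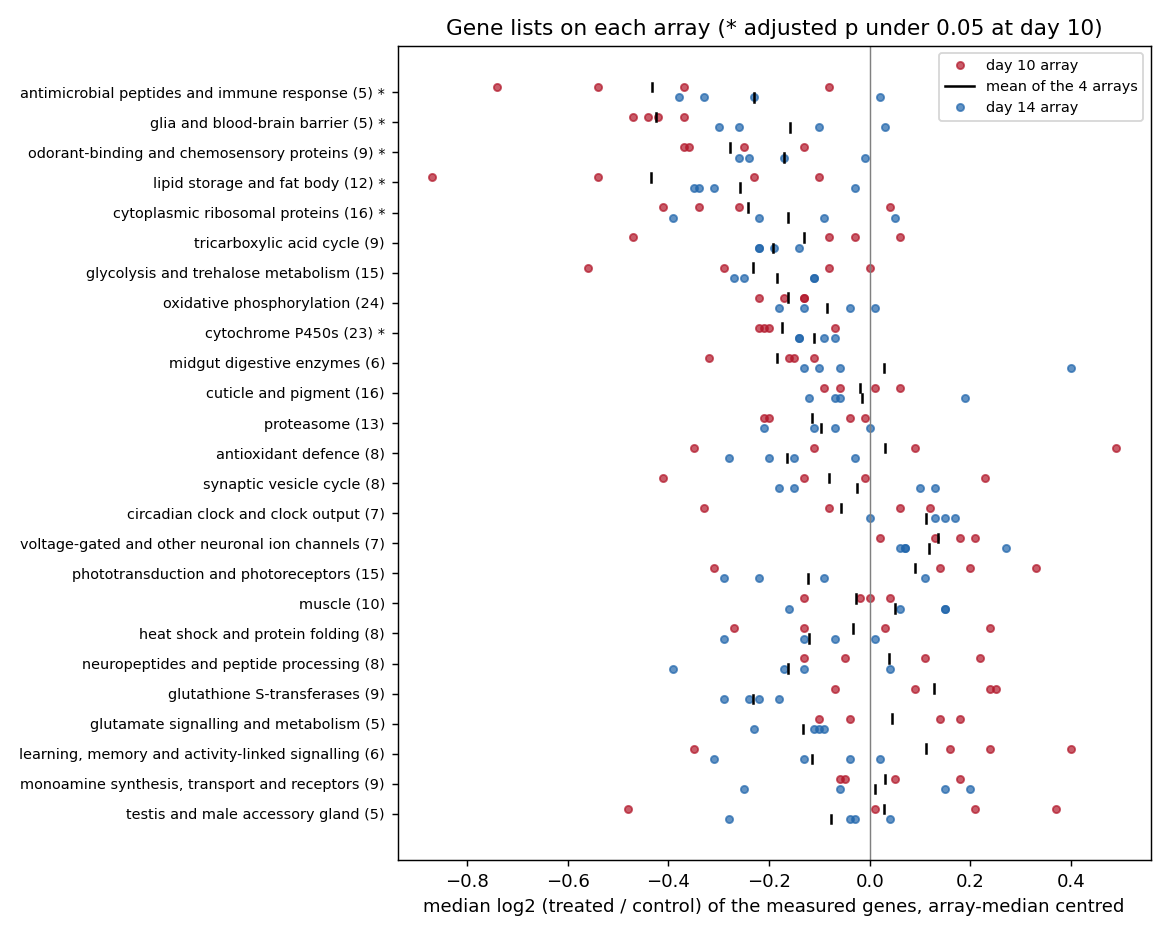
Median log2 ratio of each gene list on each array, relative to the array median, with day 10 in red, day 14 in blue and an asterisk where the list passed at day 10 after array-median centring. The fat body list has day-10 medians of -0.23, -0.10, -0.87 and -0.54.

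Few genes were higher at day 10. Past the threshold as deposited were Ars2, an RNA-processing gene, the autophagy gene Atg9, the topoisomerase gene Top3beta, the cysteine desulfurase gene Nfs1, the mitochondrial ribosomal gene mRpL54, and Osi14, Sclp and CG9839. After centring Ars2 had 0.97 ± 0.16 and Top3beta had 0.78 ± 0.12 (adjusted p = 0.0212 and 0.011). Another tested clone of Ars2 had 0.319 as deposited and 0.536 after centring and passed in neither (limma adjusted p = 0.131 and 0.0627). The clones of this group lay together on the slide: 38 of the 38 clones higher after centring, and 17 of the 18 higher as deposited, were printed in the first 16 blocks, which held 40.1% of the clones tested. Lower clones were placed unevenly too, with 26 of 100 after centring (26%) and 157 of 620 as deposited (25.3%) in those blocks. Among the clones lower after local centring, 30 of 56 lay there (53.6%, against 40.8% of the clones tested). After local centring Ars2 had 0.57 and Top3beta had 0.28 (adjusted p = 0.1 and 0.316), and 4 clones were higher, 1 of them among the 38. Osi14 was the one gene named here that passed after local centring, at 0.95 ± 0.14 (adjusted p = 0.0233), though not after array-median centring (0.85, adjusted p = 0.0563).

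In total 638 of 4563 clones passed at day 10 as deposited, 18 higher and 620 lower, which is 97.2% lower. After centring 138 passed, 38 higher and 100 lower (72.5% lower), and all 100 were among the 620. After print-block centring 117 passed, 10 higher and 107 lower (91.5% lower), and after local centring 60 of 4255 passed, 4 higher and 56 lower (93.3% lower), of which 41 were among the 100. Fitted without the day-14 arrays, day 10 gave 238 clones as deposited, 2 after centring, 0 after print-block centring and 26 after local centring. Counts as deposited dropped to 226, 385 and 345 without day-10 replicates 1, 2 and 4 and to 414 and 401 without day-14 replicates 3 and 4. Centred counts were 3, 58, 90 and 57 without day-10 replicates 1 to 4 and 55 each without day-14 replicates 3 and 4. Locally centred counts were 19, 5 and 27 without day-10 replicates 1, 3 and 4 and 31 and 23 without day-14 replicates 3 and 4. These shares rest on the direction of the ratio. With the ratios read as already turned to treated over control, 11 clones passed as deposited, 2 higher and 9 lower (81.8% lower), and 1, higher, passed after array-median and after local centring.

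**Figure D3:**
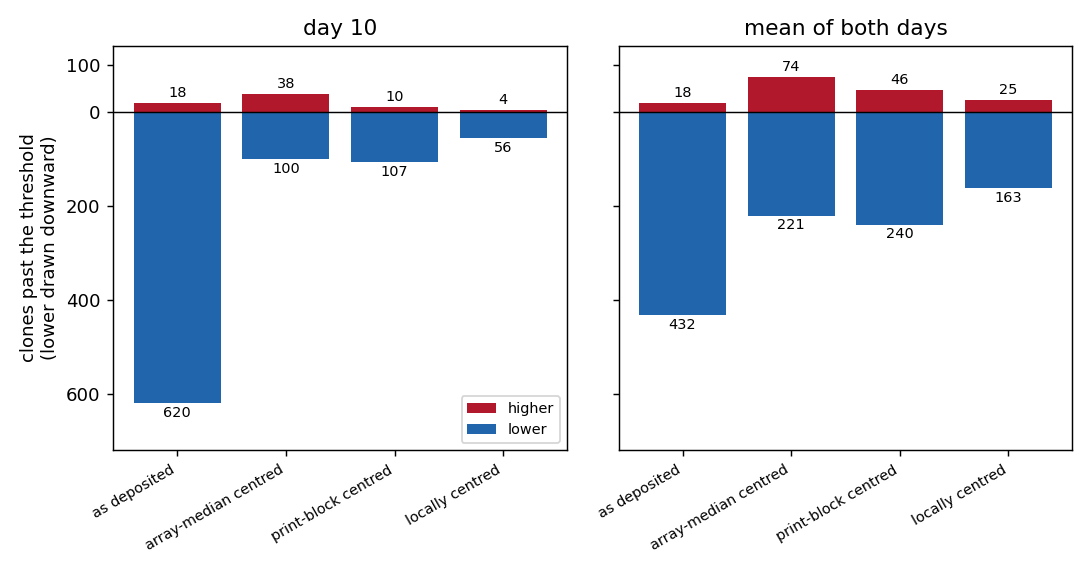
Numbers of clones past an adjusted p of 0.05, higher (up) and lower (down) in treated heads, at day 10 and over both days under 4 ways of centring. At day 10 lower clones numbered 620 as deposited, 100 after array-median centring, 107 after print-block centring and 56 after local centring.

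At day 14, after 4 days without drugs, no single gene passed the threshold in the fit of all 8 arrays. That result changed when day 14 was fitted alone, as given below. The lowest ratios were those of CG2233 at -0.90 ± 0.23, Cyp313a1 at -0.90 ± 0.18 and Drs at -0.88 ± 0.14 relative to the array median (limma adjusted p = 0.13 for each). The uncharacterised genes CG4757 and CG9689 had -0.88 and -0.83, and LManII, a lysosomal mannosidase gene, had -0.80 (adjusted p = 0.153, 0.13 and 0.13). At day 10 LManII had -0.05. The highest ratios were those of Osi6 at 1.00, CG4040 at 0.91, the nucleoporin gene Nup214 at 0.90, CG31846 at 0.88, the endoribonuclease gene Regnase-1 at 0.83 and the sorting nexin gene Snx1 at 0.82 (adjusted p between 0.13 and 0.159). Gad1 and Lcch3 had -0.21 and -0.28 (adjusted p = 0.444 and 0.565).

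By limma 0 of 4563 clones passed at day 14, with 802 at an unadjusted p under 0.05 as deposited and a smallest adjusted p of 0.166. Counts were also 0 after array-median centring (880 unadjusted), print-block centring (760) and local centring (674 of 4255). Fitted without the day-10 arrays, day 14 gave 521 clones as deposited, 531 after centring, 554 after print-block centring and 19 after local centring. The fit of all arrays shares 1 estimate of the spread per clone across both days. With each day alone after centring, the median residual SD was 0.215 at day 10 and 0.152 at day 14. The contrast in calls between the days thus depends on the fit chosen. With array weights the day-14 count was 158 as deposited, 243 after centring and 27 after local centring, and with arrays scaled to one spread it was 135. Leaving out day-10 replicate 1 gave 3 clones as deposited. No list passed, with a smallest adjusted p of 0.105 as deposited, 0.0726 after centring and 0.131 after local centring. Print-block centring brought the immune list past the threshold (adjusted p = 0.0421). Without day-14 replicate 1, 3 lists passed and without day-10 replicate 1, 1 list passed, as deposited.

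The difference between the days was tested directly. For the list of fat body genes the median difference, day 14 minus day 10, was 0.56 as deposited and 0.30 after centring, and neither passed (adjusted p = 0.497 and 0.323). After centring 8 of its 12 genes had a difference above 0 and 4 below. The 4 genes lowest at day 10 had centred ratios of -0.68 and 0.35 (apolpp), -0.91 and -0.21 (Obp99b), -0.90 and -0.61 (Lsp2), and -0.77 and -0.27 (Adh) at days 10 and 14, which a selection at day 10 alone can bring nearer to 0. After local centring, a setting chosen after seeing the data, the difference of 0.33 passed (adjusted p = 2.5e-05, and adjusted p = 7.33e-06 with an estimated correlation), with 9 of 11 genes above 0. Per array, the locally centred list median was -0.61, -0.09, -0.92 and -0.72 at day 10. At day 14 it was 0.2, -0.15, -0.37 and -0.34, so the arrays of both days overlapped. Those p-values do not measure this variation between arrays. With the ratios read as already turned, that locally centred difference was 0.057 and did not pass (cameraPR adjusted p = 0.808). Of single clones 0 of 4563 differed by limma as deposited, with 1234 at an unadjusted p under 0.05. Counts were 0 after array-median centring (485 unadjusted), print-block centring (353) and local centring (286). They were 20 as deposited without day-10 replicate 3, 8 with array weights and 1 after local centring without day-10 replicate 4. At a true log2 difference of 0.5 the test recovered 9% of simulated changes, so smaller differences would mostly be missed.

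Averaged over both days, 221 clones were lower after centring, among them 94 of the 100 that were lower at day 10. The average includes the day-10 ratios, so this overlap is partly built in. CG2233 fell by 1.24 ± 0.16, CG16926 by 1.00 ± 0.17, sxe2 by 0.80 ± 0.10 and Miox by 0.80 ± 0.13 relative to the array median (n = 7 to 8 arrays, limma adjusted p = 0.00604, 0.0144, 0.0074 and 0.0104). Lsp2, Drs, Tret1-1 and Drsl5 fell by 0.76, 0.72, 0.64 and 0.57 (adjusted p = 0.0102, 0.0102, 0.0035 and 0.00829). Smaller decreases were those of Cyp4e2 (-0.56, adjusted p = 0.0138), Gpdh1, the glycerol-3-phosphate dehydrogenase gene (-0.53, adjusted p = 0.0181), and Obp57c (-0.38, adjusted p = 0.0214). All 11 genes of this paragraph also passed as deposited and after local centring.

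As lists over both days, fat body (adjusted p = 0.00461; adjusted p = 0.0117 with an estimated correlation) and glial genes (adjusted p = 0.00305; adjusted p = 0.0247 with an estimated correlation) were lower as deposited. Immune genes had adjusted p = 0.00157 (adjusted p = 0.0995 with an estimated correlation). Of the fat body list 4 of 12 fell over all genes tested and 5 when adjusted over the list alone. For immune genes these counts were 3 and 4 of 5, and for glial genes 3 and 3 of 5. After centring they were 3 and 4 for fat body, 3 and 3 for immune and 2 and 3 for glial genes. All 3 lists also passed after centring (adjusted p = 0.00256 for fat body, 0.000654 for immune and 0.00256 for glial genes) and after local centring (7.68e-05, 0.00251 and 0.0292). Ribosomal, odorant-binding, P450, glycolytic and tricarboxylic acid cycle genes passed as deposited (adjusted p = 0.00461, 0.00593, 0.0129, 0.0221 and 0.0221), with adjusted p = 0.175, 0.0995, 0.336, 0.199 and 0.0563 with an estimated correlation. After centring these 5 lists had adjusted p = 0.00294, 0.00394, 0.0161, 0.0406 and 0.0316, and with an estimated correlation 0.00304, 0.00304, 0.18, 0.411 and 0.0272, so the P450 and glycolytic lists did not pass there. After local centring none of the 5 passed (adjusted p = 0.0555, 0.304, 0.0803, 0.186 and 0.44).

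Over both days 450 clones passed as deposited, 18 higher and 432 lower (96% lower), and 295 passed after centring, 74 higher and 221 lower (74.9% lower). After print-block centring 286 passed (83.9% lower), and after local centring 188 of 4255 passed, 25 higher and 163 lower (86.7% lower). All 3 kinds of value, as deposited, centred and locally centred, gave 102 clones in common, 100 lower and 2 higher. The count as deposited was 299 without day-10 replicate 4 and 260, 174 and 186 without day-14 replicates 2, 3 and 4. The centred count was 148 and 176 without day-10 replicates 1 and 4 and 191, 156, 86 and 27 without day-14 replicates 1 to 4. The locally centred count was 98 and 96 without day-10 replicates 1 and 3 and 104, 83, 81 and 51 without day-14 replicates 1 to 4. Read as already turned, the ratios gave 170 clones as deposited, 7 higher and 163 lower (95.9% lower), 20 after centring, 16 higher and 4 lower (20% lower), and 4 after local centring, all higher.

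Across clones, the ratios of both days were related with a Pearson coefficient of 0.32 and a Spearman coefficient of 0.31 over 4563 clones, which are not independent replicates. Controls were not shared between the days. Among the 100 clones lower at day 10 after centring, 98 were below 0 at day 14, with a median of -0.71 at day 10 and -0.34 at day 14 (of the 56 lower after local centring 52 were, and of the 620 lower as deposited 497 were, 80.2%). Among the 38 higher clones 17 were above 0 at day 14, with medians of 0.68 and -0.03 (as deposited 9 of 18). A selection at day 10 alone can bring such day-14 medians nearer to 0. Of all clones tested, 61% had the same sign on both days after centring, 62.9% after local centring and 48.8% as deposited. Because no clone passed at day 14 in the fit of all arrays, no overlap of those calls could be formed. In a comparison added after the results were seen, with day 14 fitted alone after centring, its 273 lower clones shared 47 with the 100 lower at day 10, where independent lists would share 6, and its 258 higher clones shared 1 with the 38, where independent lists would share 2.1. As deposited the shared clones were 97 lower (23.9 if independent) and 0 higher (1.4), and after local centring 2 lower (0.2) and 0 higher. The day-10 calls took their spread and dye term partly from the day-14 arrays, so these lists do not come from separate arrays. The Pearson coefficient was 0.10 without day-10 replicate 3, and 0.33, 0.39 and 0.38 after array-median, print-block and local centring.

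**Figure D4:**
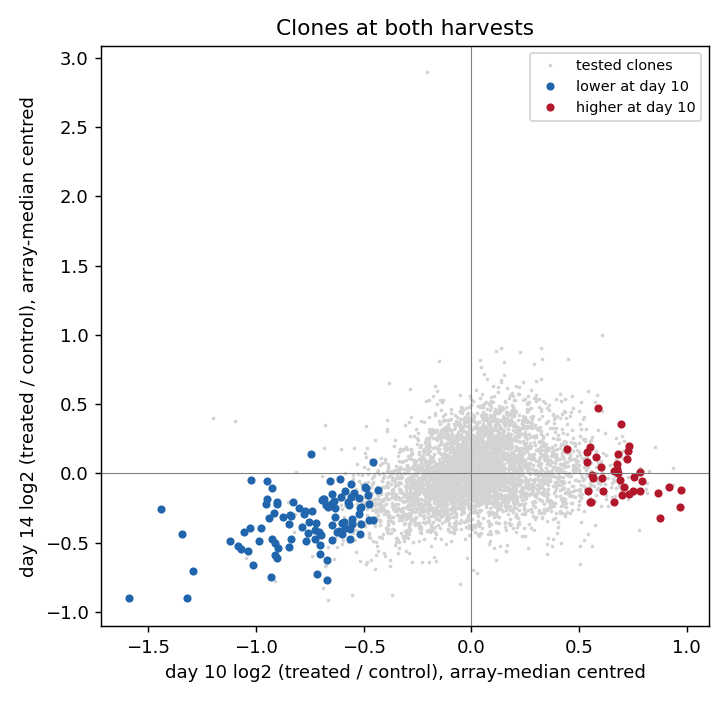
Fitted log2 ratios of 4563 clones at day 10 (horizontal axis) and day 14 (vertical axis) relative to the array median, with the 100 clones lower at day 10 in blue and the 38 higher in red. Of the blue clones, 98 also lie below 0 at day 14, and of the red clones, 17 lie above 0.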

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

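The tests in this part on slide position, on day 14 fitted alone and on the fat body list, all values with local centring and the counts over other splits of the arrays were chosen only after the results were seen, while the comparisons of single arrays with the rest followed a rule set beforehand.

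The clones higher at day 10 after centring lay together on the slide. A slide position bias is a candidate explanation: 1 of the 38 clones still passed after local centring, and the median went from 0.68 (SD 0.125, median SE 0.132) to 0.19 (SD 0.164, median SE 0.111), so the calls ended because the ratios shrank and not because their error grew. The later values cover the 37 of these clones that had a local value. Of the 100 lower clones, with a median of -0.71, the 89 with a local value had a median of -0.62 after the same centring. The lower clones were placed unevenly too, with 26 of 100 in the first 16 blocks, which held 40.1% of the clones tested. That drop to 0.19 also argues against transcripts that rose each on its own wherever printed, as the whole cause, since those would keep most of their ratio. A response shared by clones printed next to each other stays open and was not tested.

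At day 14, 531 clones passed after centring when that day was fitted without the day-10 arrays. That fit takes its spread from the day-14 arrays alone, where the median residual SD was 0.152, against 0.215 for day 10 alone. Local slide patterns shared by arrays of a dye orientation cannot be told apart from other causes. Of the 488 with a local value 16 passed after local centring, but the median absolute ratio went only from 0.438 (SD 0.139, median SE 0.098) to 0.333 (SD 0.187, median SE 0.092). The calls thus ended with somewhat smaller ratios, and also with fewer prior degrees of freedom in limma (7.14 before and 4.44 after). A response that persisted from day 10 cannot be told apart either, because the share of these clones with the sign of day 10 depends on the centring. It was 76.1% of the 531 after array-median centring (404 clones, 95% limits 72.2% and 79.7%), against 58.4% of the 4032 clones that did not pass, but 47.6% of the 521 as deposited (limits 43.2% and 52%), against 48.6% of the 4042 others. As deposited, 164 of the 176 lower and 84 of the 345 higher clones had that sign. After local centring 18 of 19 clones had it (94.7%, limits 74% and 99.9%), against 62.6% of the 4236 others. These limits treat clones as independent, which neighbours on the slide are not, and slide patterns common to both days would also give shared signs.

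Fat body genes were lower at day 10. Slide position as the whole cause is argued against by a list median of -0.546 after local centring, which passed. A smaller share of fat body in the treated heads, as the whole cause, would lower alike those markers expressed in fat body alone. The 8 measured of 18 marker genes ran from -1.18 to 0.31 after local centring. The value of 0.31 was that of Yp2, a yolk protein gene whose use as a marker in male heads is doubtful. Without Yp2 the markers ran from -1.18 to -0.145, all below 0. The heterogeneity of the markers exceeded their limma standard errors (Cochran Q 84, chi-square p = 2.08e-15, and Q 39.1, p = 6.79e-07 without Yp2). Expression of these genes outside fat body was not measured, so this spread does not decide whether that share fell. Reduced feeding on drug food cannot be told apart from other causes, since 2 of 8 genes raised by fasting were measured (median -0.234), and dye bias cannot either, if the deposited values had been turned already, since 11 of 16 pairs of opposite orientation correlated above 0, which leaves the direction unsettled. A direct response to the drug sequence stays open and was not tested separately.

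Single arrays stood apart from the other 3 of their day in 6 of 171 groups of 4 arrays, where chance gives about 5%. At day 10, replicate 4 had -1.78 for Cyp28d1 (others -0.64 to -0.44) and -1.13 for GstE12 (others -0.65 to -0.61). At day 14, replicate 2 had -0.79 for Scsalpha1 (others -0.22 to -0.14) and -0.84 for Rpt3 (others -0.06 to 0.09). Day-14 replicate 1 had -0.02 for RpL23 (others 0.06 to 0.07) and a Spearman coefficient between duplicate spots of 0.84 (others 0.67 to 0.69).

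The genes Top3beta, Gli and levy and the muscle list lay on one side of 0 on every array of one day and on the other side on every array of the other day. As deposited, the day-14 mean minus the day-10 mean was -0.64 for Top3beta (0.56 and -0.07 at days 10 and 14), 0.83 for Gli (-0.60 and 0.23), 0.67 for levy (-0.50 and 0.17) and 0.34 for the median of the muscle list (-0.24 and 0.10). These differences between the days were not tested as single values, and in the test over all clones and lists none passed. The median difference of all clones as deposited was 0.283, and after array-median centring the muscle list had means of -0.03 and 0.05 at days 10 and 14, with arrays on both sides of 0 on each day. In that setting Gli alone kept all arrays of each day on opposite sides. The fat body list differed between the days after local centring, by 0.334 (adjusted p = 2.5e-05), while 0 lists differed as deposited or after array-median centring. Its locally centred medians on single arrays overlapped between the days. With the ratios read as already turned, the fat body list did not differ after local centring (0.057, adjusted p = 0.808). Locally centred, 2 lists differed instead of 1 without day-10 replicate 4 or without day-14 replicate 2.

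Other splits of the arrays were counted for each test. For genes at day 10 the 3 splits of a day's arrays are too few for a share under 0.05, with 638 clones as deposited and 138 after centring in the real split (1 of the 3) and 0 as the highest other. For lists at day 10 the real split gave 6 and the highest other 0, and for genes and lists at day 14 all 3 splits gave 0, again too few. Over both days 18 splits keep 2 arrays of each dye orientation in each day, as the real one does, and these are again too few. The real split gave 450 clones as deposited, with 9 as the highest other, and 295 after centring and 188 after local centring, each with 0 as the highest other. For the difference between the days the real counts were 0 clones and 0 lists, which all 18 such splits reach by necessity (highest others 1 and 1), so nothing follows about chance. The 18 splits are also too few for the 1 list that differed after local centring, where 2 of them gave as many and the highest other was 1. A split of the arrays by dye orientation instead of day, which is not among the 18, gave 135 clones as deposited, but 6 after array-median centring, 1 after print-block centring and 0 after local centring. For lists it gave 1, 0, 4 and 3 in the same order. Under the direction taken here, this split measures the gene-specific dye effect, for which the main model already holds a term.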

How the results depend on the processing

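Local centring, print-block centring, tests on clones with 1 gene, tests without the 2 arrays with the fewest spots, gene lists on ratios read as already turned, and every alternative that joins centring to another choice were chosen only after the results were seen. The cause was not tested for any change below unless a reason is given. Depth limits these results through missing spots, since the arrays with the fewest values were day-10 replicate 4 and day-14 replicate 1 and signal over background is not known.

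The count of 638 clones at day 10 was 268 without a dye term, 238 with each day fitted alone, 11 with ratios read as already turned, 138 with array-median centring, 117 with print-block centring and 60 with local centring. It was 1170 at a threshold of 0.10, 300 over clones with 1 gene (fewer were tested), and 280 without the 2 arrays with the fewest spots. With array-median centring added it was 57 without a dye term, 67 with array weights, 1 read as already turned, 2 with each day alone, 419 at the threshold of 0.10 and 0 without those 2 arrays. With print-block centring and each day alone it was 0. With local centring added it was 47 without a dye term, 28 with array weights, 26 with each day alone, 1 read as already turned and 3 without those 2 arrays. Robust variance estimation, array weights, scaling, the missing-value filters and single spots kept it within 1.5 times. With 1 array left out it ranged from 226 to 684 as deposited, from 3 to 143 after array-median centring (3, 58, 90 and 57 without day-10 replicates 1 to 4, then 140, 143, 55 and 55 without day-14 replicates 1 to 4) and from 5 to 64 after local centring (19, 46, 5 and 27, then 60, 64, 31 and 23).

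The count of 0 clones at day 14 was 521 with each day alone, 135 with arrays scaled to the same median absolute deviation and 158 with array weights. It was 531 and 554 with each day alone after array-median and print-block centring, 243 with array weights after array-median centring, and 27 and 19 after local centring with array weights and each day alone. With 1 array left out it ranged from 0 to 3 as deposited and from 0 to 1 after local centring. Of clones that differ between the days, 8 passed with array weights, 1 with clones measured on all 8 arrays and 1 with local centring and array weights, and with 1 array left out from 0 to 20 as deposited and from 0 to 1 after local centring.

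The count of 450 clones over both days was 199 without a dye term, 170 read as already turned, 295 with array-median, 286 with print-block and 188 with local centring. It was 757 at a threshold of 0.10, 232 over clones with 1 gene and 281 without the 2 arrays with the fewest spots. After array-median centring it was 127 without a dye term, 20 read as already turned and 97 without those 2 arrays, and after local centring 114, 4 and 94 in the same settings and 160 with array weights. With 1 array left out it ranged from 174 to 430 as deposited, from 27 to 241 after array-median centring (148, 226, 241 and 176 without day-10 replicates 1 to 4, then 191, 156, 86 and 27 without day-14 replicates 1 to 4) and from 51 to 185 after local centring (98, 185, 96 and 138, then 104, 83, 81 and 51).

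The 6 lists at day 10 became 1 over clones measured on all 8 arrays (fewer members), 2 with an estimated correlation, and 3 with local centring and either array weights or an estimated correlation. They ranged from 3 to 7 with 1 array left out, as deposited and after array-median centring, and from 1 to 4 after local centring. With the preset correlation and leaving aside the clones measured on all 8 arrays, the fat body list passed at day 10 in 38 of 41 settings, the immune list in 37 of 41 and the glial list in 34 of 41. Each failed in the 3 settings read as already turned, where the day-10 lists past the threshold numbered 0 as deposited, 0 after array-median centring and 1 after local centring (glycolysis, higher). The immune list also failed after local centring without day-10 replicate 2, and the glial list after local centring without day-10 replicate 1, 2 or 3 and after array-median centring without day-10 replicate 4. At day 14 the 0 lists became 1 read as already turned (ribosomal, higher), 1 with print-block centring and 0 to 3 with 1 array left out (0 to 1 after local centring). Lists that differ between the days numbered 1 with fry as deposited (oxidative phosphorylation, fry adjusted p = 0.00207). Fry tests a list against 0, where the median log2 difference of all clones as deposited was 0.283. After array-median centring that list did not pass (fry adjusted p = 0.683). By cameraPR, lists that differ between the days numbered 1 with print-block centring, and 1 with local centring alone or with array weights, an estimated correlation or without the 2 arrays with the fewest spots, and 2 with local centring and either no dye term or a replicate block. With 1 array left out they were 0 as deposited and 1 to 2 after local centring. Read as already turned, they were 0 as deposited, after array-median centring and after local centring. The correlation between the days, 0.32, was 0.195 over clones on at least 2 arrays of each day and 0.15 with local centring read as already turned, and ranged from 0.104 to 0.381 with 1 array left out (0.124 to 0.382 after array-median and 0.137 to 0.417 after local centring).

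The values gave no clear pairing by replicate number. Same-numbered arrays of both days had correlations of deviations of 0.06, 0.21, 0.12 and 0.23. Replicates 2 and 4 correlated best with their own number, and replicates 1 and 3 did not. Pairs of the same dye orientation lay above 0 and pairs of opposite orientation below, so these correlations cannot exclude a shared batch. As a replicate block the number holds the dye orientation. With the replicate block 460 clones passed at day 10 as deposited, 57 after array-median and 56 after local centring, 117 and 114 passed over both days after these centrings, and 2 lists differed between the days after local centring.

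Read as already turned, 19 named ratios at day 10 changed sign: Osi14 -0.014, CG9839 -0.17, Nfs1 -0.141, CG2233 0.117, CG16926 0.006, mRpS34 0.307, apolpp 0.27 and 0.43 (both clones), Cyt-b5-r 0.216, Cyp28d1 0.303, GstE12 0.107, UGP 0.302, Pgi 0.135, Scsalpha1 0.107, RpL23 0.201, RpL15 0.111, Lsp2 0.104, Adh 0.263 and Act79B 0.137. After array-median centring 34 of the 63 named day-10 calls had the opposite sign in that reading, and 0 passed. With local centring, CG9839 had -0.041 with each day alone, -0.006 without the 2 arrays with the fewest spots, and -0.016, -0.066, -0.006, -0.002, -0.003 and -0.005 without day-10 replicates 1 and 2 and day-14 replicates 1 to 4. Ogdh had 0.048 without day-10 replicate 1 and Pgi had 0.024 without day-10 replicate 3, with local centring.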

Other observations

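The gene selection and the day-14 values in this part were chosen only after the values were seen, and no test was added beyond those already described.

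Over both days 61 named genes were lower and 1 was higher on all 3 kinds of value, as deposited, centred and locally centred. Among those not yet described, ppl, a component of the glycine cleavage system, fell by 0.52 ± 0.10 relative to the array median, and Papss, which makes the sulfate donor of sulfotransferases, fell by 0.67 ± 0.16 (limma adjusted p = 0.0175 and 0.0455). Paics of purine synthesis fell by 0.55 ± 0.11, the transaldolase gene Taldo by 0.47 ± 0.10, the acetyl-CoA synthase gene AcCoAS by 0.38 ± 0.07 and the argininosuccinate synthase gene Ass by 0.63 ± 0.09 (adjusted p = 0.0227, 0.0223, 0.0175 and 0.0102). Jhbp13 and Jhbp14, of the family of juvenile hormone binding proteins, fell by 0.63 ± 0.11 and 0.59 ± 0.08, and smp-30, a regucalcin-like gene, fell by 0.58 ± 0.08 (adjusted p = 0.015, 0.00652 and 0.00764). The higher gene was Osi6, with 0.80 ± 0.12 after centring and 0.45 ± 0.10 after local centring (adjusted p = 0.0102 and 0.046).

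With day 14 fitted alone after local centring, 19 clones passed. Among the lower ones were CG2233 at -0.94, the polyol dehydrogenase gene Sodh1 at -0.90, LManII at -0.86, Cyp4e2 at -0.78 and Drs at -0.74, and among the higher ones were Nup214 at 1.06, Snx1 at 1.04, COX6CL at 0.89 and Regnase-1 at 0.83 (limma adjusted p between 0.0477 and 0.0496). None of these passed at day 14 in the fit of all 8 arrays, where the smallest adjusted p after local centring was 0.0731.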
